A study of Caenorhabditis elegans with 5 samples.

How the data were processed

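The study measured RNA in 5 libraries of C. elegans, 1 per group: control of day 3, gld-1 RNAi of day 3, gld-1 RNAi fasted, gld-1 RNAi fed on L4440 bacteria, and young adults of day 1. Groups follow the sample titles. The growth protocol in the labels places L1 larvae on control or gld-1 RNAi food, whereas the description of the gld-1 RNAi sample has the animals moved to gld-1 RNAi food after day 1 of adulthood, so the length of the RNAi treatment is not settled here. The labels give both mRNA and total RNA as the material, and neither a poly(A) step nor the strandedness of the libraries is given in the sources used here.

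Per the submitters' processing notes, reads were processed with TopHat, HTSeq and DESeq, for which no version is given. The genome build is not given in the sources used here, so no coordinates are printed. The authors deposited 5 tables, each for 1 pair of libraries, with 2 columns of normalized signal per gene, the log2 fold change and an adjusted p-value, per the file headers. The signal values deposited by the authors are gene counts divided by a size factor set within each pair. Which column holds which library was taken from the order of the names of each table and DESeq's column order. Whole reads were recovered from the step between low values: 100% of the values above 0 came out whole within 0.1 read, and a library that recurs in several tables gave equal reads for every gene (0 genes differed), as the column assignment requires. The gld-1 RNAi library of day 3 stands in 4 of the 5 tables, so those comparisons share its chance values, and agreement between them is no independent support. The same holds for the fed and the fasted library, which also recur. The overlap used control to gld-1 RNAi and fed to fasted, which share no library.

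The files list 45461 gene identifiers, WormBase sequence names, of which 44936 were matched to gene names through the RefSeq locus tags and the Ensembl release 115 annotation of WBcel235, used for names, biotypes and exon lengths only. The 525 others kept their identifier and held at most 0.368% of the reads of any library. Members of the mitochondrial genome list were taken as its protein-coding genes in that annotation. With 1 library per group no model has residual degrees of freedom, so no count model could be fitted to the recovered reads, and no p-value, standard error or replicate check is given. An adjusted p printed in the text is the authors' own, from their deposited table. With 1 library per group it has to take the spread from the 2 conditions themselves, so it does not measure variation between pools. Folds were computed within a table as log2 of the second value plus 1 over the first value plus 1, which understates changes of low genes, for genes with a mean of at least 50 normalized reads, and genes at least 2-fold apart were counted. For a ratio of reads in 2 libraries, 95% intervals are exact (Clopper-Pearson); they cover counting error only. At 50, 100 and 1000 reads in each library the interval reaches 0.60, 0.41 and 0.13 on either side of the log2 ratio. A gene with 0 reads in 1 library was set against a floor of 3 reads.

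A set of 39 gene lists with 1222 entries, 1179 of them matched, was fixed before the data were examined, as were the rule for named genes and the alternatives below except where stated. A list with at least 5 measured members stands apart when its median lies below the 2.5 or above the 97.5 percentile of 10000 random lists, each member replaced by a gene of the same of 20 expression bins. By chance 5% of lists would if their members varied independently, as those of the random lists do. Members of 1 list may vary together, so more lists could stand apart without any effect of the condition. The percentile places a list within these libraries and does not test the condition. Named genes were, per comparison, gld-1, the 8 highest and 8 lowest folds among genes with a gene name and a mean of at least 100, up to 4 leading members of each list that stood apart, 13 genes chosen in advance (the autophagy, lipid, germline and neuronal genes hlh-30, lgg-1, bec-1, unc-51, daf-16, nhr-49, lipl-4, fat-6, fat-7, glp-1, rme-2, vit-2 and unc-119) and up to 2 members of the 5 highest and 5 lowest name families with at least 10 measured members. The alternatives were scaling to equal totals or equal upper quartiles, minimum means of 10 and 200, a pseudocount of 10 or none, an adjusted p of 0.05, an indirect fed to fasted contrast through the gld-1 RNAi tables, and overlaps at 1.5-fold and 3-fold. Scaling to the total without rRNA and counts of genes whose counting interval lies wholly beyond 2-fold were added after seeing the data. For levels over all 5 libraries the recovered reads were divided by median-of-ratios size factors. Reads shared by near-identical copies (histone, major sperm protein, hsp-16, vit-3 and vit-4, fat-6 and fat-7, col genes) may be split between them or lost, and overlapping or antisense genes cannot be told apart without strand, so single members of these families are uncertain.

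The functions were tested on simulated data with 200 changed genes per pair. Both libraries of a pair were drawn from the same mean per gene, apart from the changes, with counting error only. The shares below therefore leave out variation between pools and give no rate of false differences in the real libraries. For control to gld-1 RNAi (9789 genes) recovery gave 0 wrong reads, 98% of the genes changed by 1.5 and 98% of those changed by 2.5 on the log2 scale were found, the rest having a mean under the minimum, and 0 of 9593 unchanged genes passed 2-fold. For fed to fasted (9001 genes) 94% and 98% were found. Of 200 random lists 5% and 6.5% stood apart in these 2 pairs, and 3.5% in each of the 2 pairs of gld-1 RNAi with a day 4 library. Their members were unchanged genes picked at random, so these shares do not cover lists whose members vary together. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.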

Results

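RNA was sequenced from whole hermaphrodites of the nematode Caenorhabditis elegans kept at 20 °C, in 5 libraries that stand for 5 groups with 1 library each. Each library pooled ca. 3000 animals from 2 independent experiments, so the spread between experiments cannot be seen and no comparison has a replicate check. In 3 of the groups the animals had been fed bacteria that carry double-stranded RNA against gld-1, which encodes a germline RNA-binding protein. Loss of GLD-1 lets germ cells that should become oocytes return to mitosis and fill the gonad as a tumour. The gld-1 RNAi library came from day 3 of adulthood. A second group of gld-1 RNAi animals was moved on day 2 to plates with no food for 48 h (fasted), and another to plates with L4440 control bacteria for 48 h (fed). Both are labelled as day 4. The other 2 groups ate L4440 bacteria, which carry the empty RNAi vector, and were collected on day 3 (control) or day 1 (young adult). The gene totals were 27547808 reads in the control and 27598482 in the gld-1 RNAi library. They were 27469984 in the fed, 13803289 in the fasted and 15426039 in the young adult library. Ribosomal RNA took 28.1%, 25.7%, 27.7%, 26.6% and 3.53% of these reads in the same order. Log2 folds below are of the second library named over the first, on the authors' normalized values plus 1. Parentheses after a gene give its normalized reads in the first and second library and the log2 fold, or the log2 fold alone. Gene lists are placed by the percentile of their median among 10000 random lists of equal size and like expression.

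The RNAi target was measured first. gld-1 (T23G11.3) stood at 24395 normalized reads in the control and 2482 in the gld-1 RNAi library, a log2 fold of -3.30 (95% counting interval -3.36 to -3.24), with an adjusted p of 0.00802 in the authors' deposited table. Against the young adult library the log2 fold was -3.03. From the gld-1 RNAi to the fed library, whose animals had left the RNAi food, gld-1 was higher by a log2 fold of 0.60 (2517 to 3807 normalized reads), and from the fed to the fasted library it was lower, by a log2 fold of -0.92 (2633 to 1394 normalized reads). On 1 scale over all libraries gld-1 stood at 20340 in the control, 17593 in the young adult, 1994 in the gld-1 RNAi, 3061 in the fed and 1592 in the fasted library, as the labels would have it. RNAi food carries gld-1 sequence of its own, which can add reads in the library of animals taken from it.

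**Figure D1:**
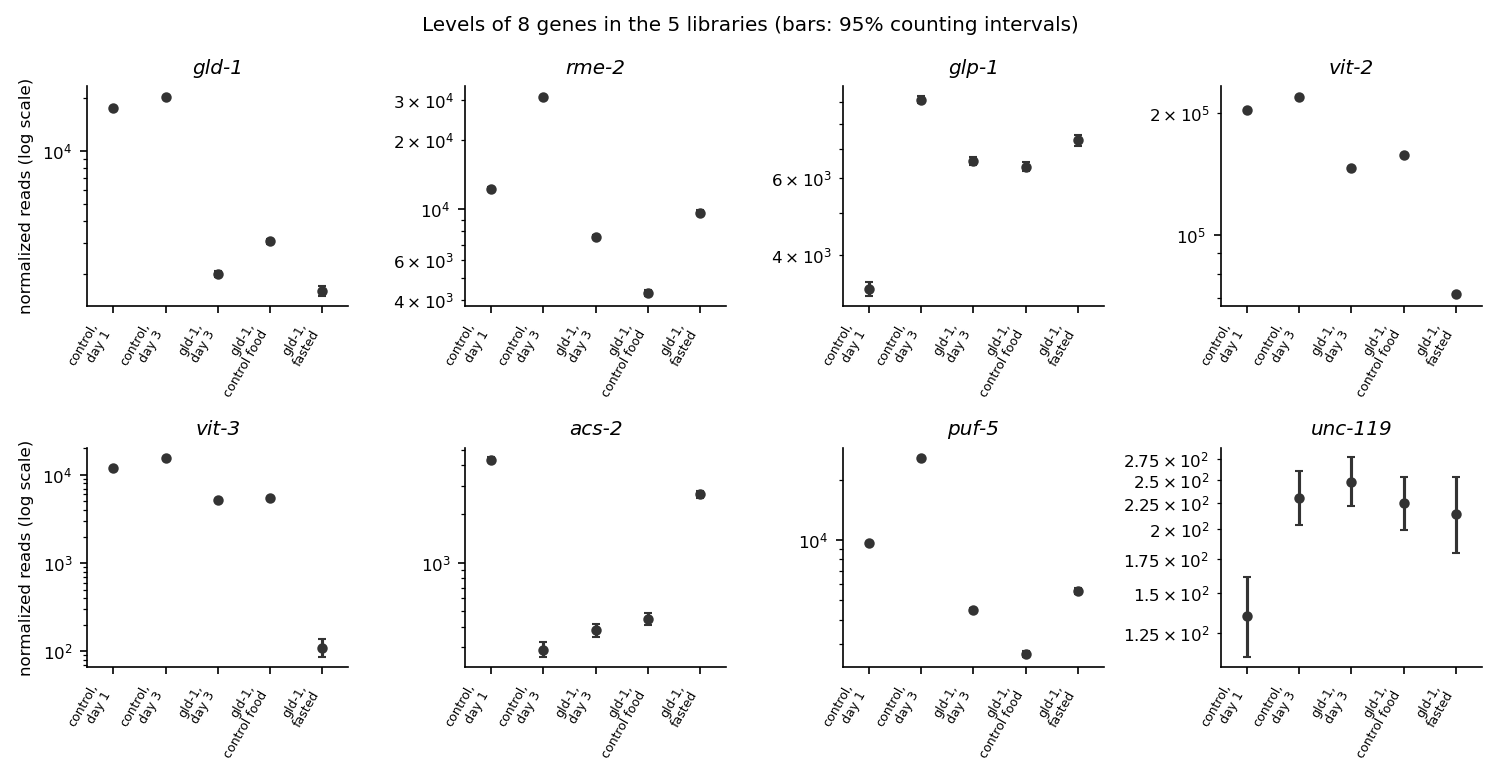
Normalized reads (log scale, 1 scale over the 5 libraries) of 8 genes in each library, with bars for 95% counting intervals, which cover counting error only and are often narrower than the point. gld-1 is lower in the 3 gld-1 RNAi libraries than in both controls. rme-2 and puf-5 are highest in the day 3 control, and vit-3 is lowest in the fasted library. acs-2 is higher in the fasted than in both other gld-1 RNAi libraries, and highest in the young adult library.

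The control and gld-1 RNAi libraries of day 3 address what a germline tumour changes in animals of the same age. Genes of the oocyte and of the early embryo were lower in the gld-1 RNAi library, and genes of ribosomes and neurons were higher. On 1 scale over the 5 libraries, oocyte genes (1.37), ribosomal proteins (-0.92) and neuronal markers (-0.95) went the other way from young adult to control. A trait of the day 3 control library is therefore not told apart from the tumour. From control to gld-1 RNAi, all 32 measured members of the oocyte list were at least 1.5-fold lower (median log2 fold -1.53, below all 10000 random lists). Among them were cpg-3 (R06C7.4, 26070 to 4270, log2 fold -2.61), an eggshell chondroitin proteoglycan, and puf-5 (F54C9.8, 30781 to 5547, log2 fold -2.47), a Pumilio-family translational repressor of oocytes. Others were egg-1 (B0244.8, 25367 to 5133, log2 fold -2.3), needed for fertilization, and the yolk receptor rme-2 (T11F8.3, 37127 to 9387, log2 fold -1.98). The list of mRNAs bound by GLD-1, of which 16 of 21 also stand in another list, had a median of -0.79 (15 of 21 at least 1.5-fold lower). Genes first transcribed in embryos had a median of -1.57 (9 of 13 at least 1.5-fold lower), with sdz-28 (R52.1, -3.27) and lsy-27 (F47H4.1, -1.70) among them. Its lowest members, tbx-38 and tbx-37, lay under the mean that the naming rule asks for and were named after their values were seen. The other germline lists did not stand apart. Germline stem cell genes had a median of -0.14 (percentile 48.6), germ granule genes 0.03 (percentile 82.4) and meiosis genes -0.02 (percentile 91), the first turning above 0 under upper quartile scaling and the last under all 3 other scalings. Genes of DNA replication and mitosis were lower (median -0.43, 18 of 45 at least 1.5-fold lower), led by the cyclin cyb-3 (T06E6.2, 22903 to 7372, log2 fold -1.64) and the ribonucleotide reductase subunit rnr-2 (C03C10.3, 19006 to 7660, log2 fold -1.31).

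Of the cytosolic ribosomal proteins, 56 of 58 measured were at least 1.5-fold higher in the gld-1 RNAi library (median 0.81), with rpl-11.2 (F07D10.1, 2566 to 11422, log2 fold 2.15) the furthest. Nucleolar and ribosome biogenesis genes had a median of 0.69 (16 of 25 at least 1.5-fold higher), among them the nucleolar GTPase nog-1 (T07A9.9, 5576 to 19391, log2 fold 1.80) and the RNA polymerase I subunit rpoa-1 (Y48E1A.1, 3768 to 10248, log2 fold 1.44). Neuronal markers had a median of 0.86 (19 of 32 at least 1.5-fold higher), for instance unc-10 (T10A3.1, 84.9 to 352, log2 fold 2.04), of the presynaptic active zone, and unc-2 (T02C5.5, 175 to 702, log2 fold 2.0), a calcium channel. The pan-neuronal unc-119 (M142.1, 277 to 309, log2 fold 0.16) had a counting interval that spans 0. All 3 of these medians lay above all 10000 random lists. Of the sperm genes few were measured, 6 of 32 in the sperm list and 0 of 30 major sperm protein genes. The former were higher (median 1.52, 5 of 6 at least 1.5-fold higher), such as fer-1 (F43G9.6, 39.8 to 440, log2 fold 3.43). A gene under 50 normalized reads in the control, such as fer-1, is measured only where it is higher in the gld-1 RNAi library. The minimum mean thus favours this direction among low genes. fog-3 (C03C11.2, 4.46), which sets germ cells on the sperm path, was among the 8 named genes with the highest folds. The other genes of that group were spp-9 (1.05 to 303 normalized reads, 1 read in the control, 95% counting interval of the log2 ratio 5.69 to 13.48), icmt-1 (F21F3.3, 5.24 to 603, log2 fold 6.60), pals-27 (B0284.2, 4.19 to 297, log2 fold 5.84) and lips-13 (T13B5.7, 3.14 to 213, log2 fold 5.69, 95% counting interval 4.52 to 8.37), the last from 3 reads in the control. They also held tbb-6 (T04H1.9, 83.8 to 2036, log2 fold 4.59), fbxa-94 (F28F8.8, 8.38 to 209, log2 fold 4.48) and spp-12 (T22G5.7, 8.38 to 196, log2 fold 4.39).

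Intestinal markers and part of the metabolic lists were lower in the gld-1 RNAi library. Intestinal markers had a median of -0.68 (10 of 16 at least 1.5-fold lower, such as the metallothionein mtl-2 (T08G5.10, -2.39)). The 6 yolk protein genes had a median of -0.82 (4 of 6, percentile 1.95), a placement that is lost at a minimum mean of 200. Medians were also below their random lists for gluconeogenesis, glyoxylate and trehalose genes (-0.65, led by the glycogen phosphorylase pygl-1 (T22F3.3, -1.89)), and glycolysis (-0.56). So were those for mitochondrial beta oxidation (-0.43, led by the acyl-CoA dehydrogenase acdh-1 (C55B7.4, -2.02)) and lysosomal genes (-0.52). The same held for proteasome subunits (-0.50, 8 of 32 at least 1.5-fold lower) and antimicrobial genes (-0.37, 18 of 43 at least 1.5-fold lower and 8 higher). Other metabolic lists did not stand apart. They were the tricarboxylic acid cycle (-0.05) and respiratory chain (-0.06), both above 0 under all 3 other scalings, peroxisomal beta oxidation (0.10), fatty acid synthesis (-0.21) and lipases (-0.41). The named genes with the lowest folds, besides gld-1 and sdz-28, included the lysozyme lys-4 (F58B3.1, 893 to 94.5, log2 fold -3.23) and dod-24 (C32H11.12, 833 to 93.5, log2 fold -3.14). They further included the collagens col-165 (F14H12.1, 319 to 9.54, log2 fold -4.92) and col-74 (ZK1248.2, 249 to 20, log2 fold -3.57), skr-9 (C52D10.7, -3.67) and sepa-1 (M01E5.6, -3.04), an adaptor of embryonic autophagy. Autophagy genes as a list did not stand apart (median -0.33, percentile 2.98). bec-1 (T19E7.3, 0.01), lgg-1 (C32D5.9, -0.17), unc-51 (Y60A3A.1, 0.04) and hlh-30 (W02C12.3, 0.14) had small folds. Body wall muscle markers stood slightly above their random lists (0.14, percentile 99.4), while pharynx (-0.32) and hypodermis (0.01) markers did not stand apart.

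Of 9791 genes with a mean of at least 50 normalized reads, 878 were at least 2-fold higher and 782 at least 2-fold lower in the gld-1 RNAi library, and 17 of 38 lists stood apart. Scaled to the same total the split was 1082 to 593, and to the same upper quartile 1098 to 579, with the median of all genes at 0.03 and 0.04 instead of -0.10. The authors' deposited table called 47 genes at an adjusted p below 0.1, 31 higher and 16 lower.

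**Figure D2:**
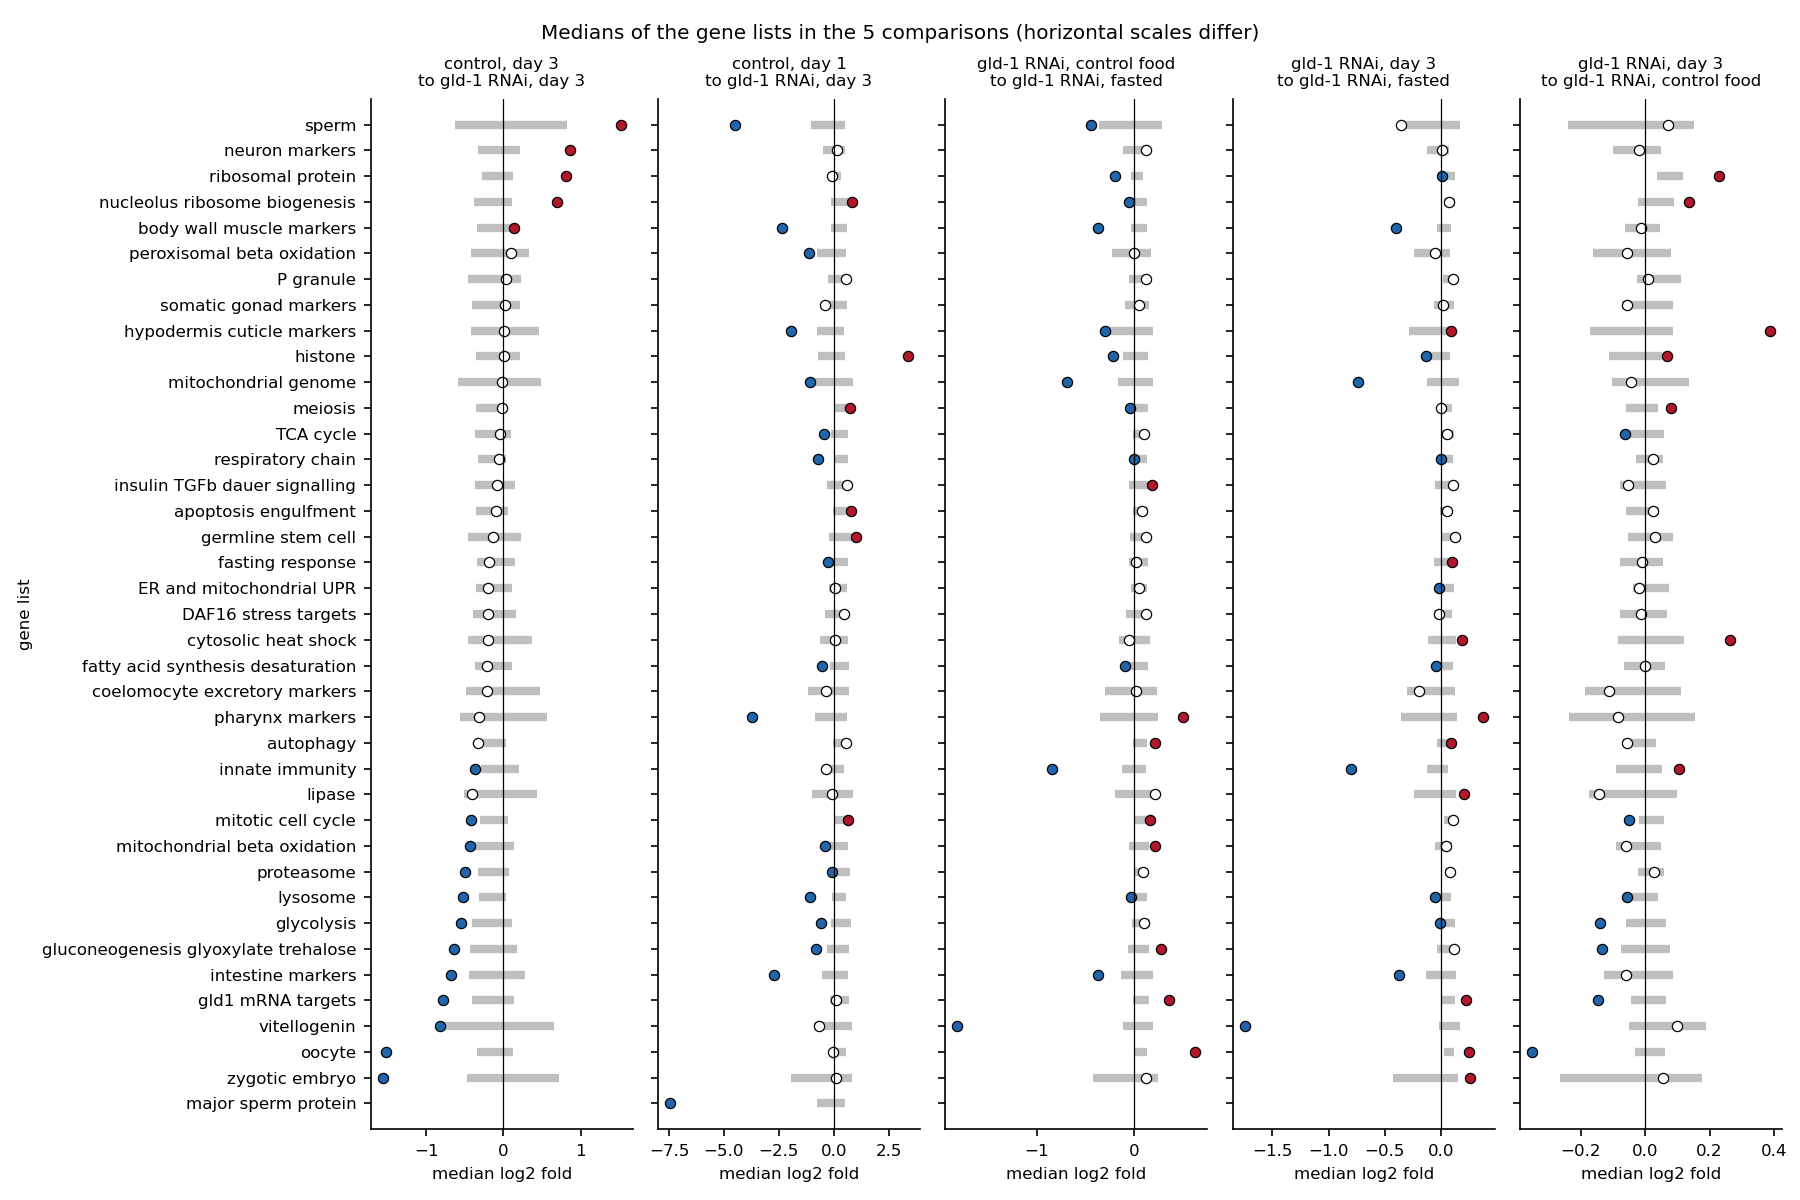
Median log2 fold of each fixed gene list in the 5 comparisons (horizontal axis, scales differ between panels). Grey bars give the central 95% of 10000 random lists matched on size and expression. Red and blue points are lists above or below that range, and white points lists inside it. The oocyte list is at -1.53 in the first panel and 0.63 in the third.

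Young adults of day 1 against gld-1 RNAi animals of day 3 set the tumour beside younger animals on control food, so that age and RNAi differ together. The day 3 control differed from the young adult library in the same direction for sperm (median -5.93), col (-4.86), mitosis (1.16) and histone genes (3.46). The same held for pharynx (-3.74), intestine (-2.19), body wall muscle (-2.63) and hypodermis markers (-2.11). Among the 5 comparisons of the deposited tables, the rRNA shares also differed most in this one, 3.53% and 25.7%. Sperm and cuticle genes were far lower in the gld-1 RNAi library. All 24 measured major sperm protein genes were at least 1.5-fold lower (median -7.46, or -7.38 with the 2 genes without a read in the gld-1 RNAi library at a floor of 3 reads). Of these, msp-53 (R13H9.4) was at least 171-fold lower. Other sperm genes had a median of -4.51 (16 of 20 at least 1.5-fold lower, such as the phosphatase gsp-3 (W09C3.6, 1000 to 7.79, log2 fold -6.83)). Of the collagens of the col family, 91 were at least 1.5-fold lower and 6 higher (median -5.35), with col-81 (F38A3.1, 44132 to 96.1, log2 fold -8.83) and col-133 (F52B11.4, 9437 to 17.3, log2 fold -9.01) among the 8 lowest named genes. Markers of the pharynx (-3.71), intestine (-2.73), body wall muscle (-2.34) and hypodermis (-1.97) had low medians as well. Examples are the peptide transporter pept-1 (K04E7.2, -5.07), the myosin light chain mlc-1 (C36E6.3, -3.73) and the cuticle gene dpy-5 (F27C1.8, -6.31). The named genes with the highest folds included lips-11 (T13B5.5), at 0 reads in the young adult and at least 132-fold higher in the gld-1 RNAi library, and dpy-14 (H27M09.4, 5.77 to 552, log2 fold 6.35).

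Higher in the gld-1 RNAi library were histone genes (21 of 26 measured at least 1.5-fold higher, median 3.39, for instance his-62 (F55G1.3, 50.8 to 1258, log2 fold 4.60)). So were germline stem cell genes (median 1.02, 10 of 15 at least 1.5-fold higher), meiosis genes (0.76) and nucleolar genes (0.85). Genes of germ cell apoptosis and the DNA damage checkpoint (0.77) were also above their random lists, and so were genes of replication and mitosis (0.67, not kept at a minimum mean of 200). Examples were fbf-1 (H12I13.4, 553 to 1787, log2 fold 1.69), a Pumilio-family regulator of germline stem cells, the meiotic kinase chk-2 (Y60A3A.12, 202 to 1504, log2 fold 2.89) and the meiotic cohesin rec-8 (W02A2.6, 1343 to 5646, log2 fold 2.07). From control to gld-1 RNAi, germline stem cell and meiosis genes did not stand apart and the histone median was 0.00. The rise of these lists from young adult is therefore not tied to gld-1 RNAi here. The oocyte list did not stand apart (median -0.03, percentile 6.61, above 0 under upper quartile scaling). Lower lists of metabolism included lysosomal genes (-1.07), the respiratory chain (-0.71), glycolysis (-0.56), the tricarboxylic acid cycle (-0.46) and fatty acid synthesis and desaturation (-0.55). At least 2-fold higher were 1876 and at least 2-fold lower 2570 of 10795 genes, but scaled to the same total over all genes, rRNA included, the split was 886 to 3473, with the median of all genes at -0.33 instead of 0.12. The authors' deposited table called 185 genes, 11 higher and 174 lower.

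The fed and fasted gld-1 RNAi libraries, both of day 4, differ in food among animals with a tumour. The level of gld-1 also differed between them (log2 fold -0.92), so food is not told apart from the strength of the knock-down. Yolk protein, antimicrobial and collagen genes were lower in the fasted library, and oocyte genes were higher. All 6 yolk protein genes were at least 1.5-fold lower (median -1.82). The lowest were vit-3 (F59D8.1, 4692 to 96.6, log2 fold -5.59), vit-4 (F59D8.2, 5213 to 336, log2 fold -3.95) and vit-1 (K09F5.2, 5566 to 964, log2 fold -2.53), and vit-2 (C42D8.2, 135511 to 62494, log2 fold -1.12) differed less. Yolk protein genes made up 2.95% of the reads outside rRNA in the fed and 1.56% in the fasted library. Antimicrobial genes had a median of -0.85 (19 of 36 at least 1.5-fold lower and 5 higher). The lysozyme lys-7 (C02A12.4, 13940 to 1251, log2 fold -3.48), the saposin-like spp-17 (C54G6.5, 569 to 60.2, log2 fold -3.22) and dod-19 (ZK6.10, -3.34) were lower. thn-1 (F28D1.3, 136 to 1807, log2 fold 3.73) and the lysozyme ilys-3 (C45G7.3, 416 to 1585, log2 fold 1.93) were higher. Of the col family, 23 of 33 were at least 1.5-fold lower (median -1.66), such as col-80 (C09G5.5, 934 to 33.6, log2 fold -4.76) and col-101 (K02D7.3, 4494 to 354, log2 fold -3.66). The other lowest named genes were acdh-1 (591 to 18.2, log2 fold -4.95), sysm-1 (T24B8.5, 553 to 18.2, log2 fold -4.85), spp-9 (T25C12.2, -4.34) and irg-8 (ZK6.11, -3.82). The 8 measured protein genes of the mitochondrial genome were lower (median -0.69, 6 of 8 at least 1.5-fold). Nuclear respiratory chain genes had a median of 0.00, below their random lists but above 0 when scaled to the total or upper quartile, and 0 of 38 were 1.5-fold lower. Body wall muscle markers had a median of -0.37 (9 of 31 at least 1.5-fold lower), ribosomal proteins -0.19 and histones -0.22, with no member of the last 2 lists 1.5-fold lower. Pharynx markers were higher instead (median 0.51, 6 of 8 above 0, percentile 100), such as dod-6 (T20G5.7, 499 to 1155, log2 fold 1.21) and the pharyngeal myosin myo-2 (T18D3.4, 377 to 647, log2 fold 0.78). Intestinal markers (-0.37) were below their random lists at the minimum mean of 50 but not of 10 or 200.

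Of the oocyte list, 18 of 32 measured genes were at least 1.5-fold higher in the fasted library (median 0.63, above all 10000 random lists). It was led by rme-2 (3703 to 8478, log2 fold 1.19), cpg-3 (1837 to 4055, log2 fold 1.14), egg-1 (2224 to 4768, log2 fold 1.1) and puf-5 (2304 to 4884, log2 fold 1.08), and perm-2 and perm-4, named after their values were seen, were the 2 members below 0. Germline stem cell (0.12) and germ granule (0.12) genes did not stand apart. Meiosis genes (-0.04, percentile 0.21) and the 6 measured sperm genes (-0.45, percentile 0.96) were below their random lists. Genes of replication and mitosis were above theirs (0.16, 41 of 45 higher, percentile 99.9), with no member 1.5-fold higher. The named genes with the highest folds were the cysteine protease cpr-2 (F36D3.9, 14.3 to 302, log2 fold 4.31), the alcohol dehydrogenase adh-1 (K12G11.3, 146 to 2839, log2 fold 4.27), thn-1 and the aquaporin aqp-1 (F32A5.5, 58.6 to 507, log2 fold 3.09). Next came the acyl-CoA synthetase acs-2 (F28F8.2, 387 to 2318, log2 fold 2.58, 95% counting interval 2.44 to 2.72), ilys-3, the carnitine palmitoyl transferase cpt-3 (Y48G9A.10, 161 to 549, log2 fold 1.76) and dpf-6 (F44B9.1, 84.3 to 258, log2 fold 1.6). Of the mitochondrial beta oxidation list, 3 of 24 genes were at least 1.5-fold higher, acs-2, cpt-3 and cpt-4, and the median was 0.21. Of its other members 9 were below 0, acdh-1 furthest. Peroxisomal beta oxidation (0.00, percentile 56.5) and lipase genes (0.22, percentile 95.6, apart at a minimum mean of 10) did not stand apart, and fatty acid synthesis and desaturation genes (-0.09, above 0 at a minimum mean of 200) stood below their random lists. Gluconeogenesis, glyoxylate and trehalose genes had a median of 0.28, led by pygl-1 (5986 to 9962, log2 fold 0.73) and the glyoxylate enzyme icl-1 (C05E4.9, 5036 to 8247, log2 fold 0.71). Autophagy genes stood above their random lists (median 0.22, 29 of 37 higher), yet none of those measured was 1.5-fold higher. lgg-3 (B0336.8, 0.48) and atg-16.2 (K06A1.5, 0.47) were highest, hlh-30 (0.30) and unc-51 (0.30) differed less, and bec-1 (-0.06) and lgg-1 (0.02) had counting intervals that span 0. Lysosomal genes as a list had a median of -0.03, above 0 at a minimum mean of 200, with the proteases asp-4 (R12H7.2, 3705 to 1305, log2 fold -1.51) and cpr-1 (C52E4.1, 4804 to 1748, log2 fold -1.46) lower. The list of known fasting-response genes did not stand apart (median 0.02, percentile 25.4), and its members went both ways, 6 at least 1.5-fold higher and 5 lower of 26. The transcription factor genes nhr-49 (K10C3.6, 0.13) and daf-16 (R13H8.1, 0.08) had small folds, and the desaturase gene fat-6 (VZK822L.1, -0.53) was lower. lipl-4 (K04A8.5, 0.70) rested on few reads and fat-7 is listed at 0 in all 5 libraries, which does not show that it is silent, since reads it shares with its close copy fat-6 may not have been counted.

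At least 2-fold higher in the fasted library were 114 and at least 2-fold lower 298 of 8991 genes, and 22 of 38 lists stood apart. The authors' deposited table called 132 genes, 24 higher and 108 lower, with adjusted p values of 9.87e-43 for vit-3, 1.65e-09 for acs-2 and 0.00797 for rme-2.

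The gld-1 RNAi library of day 3 was also set against each day 4 library, which mixes a day of age with the move to other plates. Towards the fasted library, 52 genes were at least 2-fold higher and 314 lower of 9100. The fasted library is the one of the fed to fasted pair, so agreement with that pair is no independent support. Yolk protein genes (median -1.75), antimicrobial genes (-0.80), mitochondrial genome genes (-0.74) and the col family (-2.15) were lower here too. Examples are vit-3 (-5.57), col-143 (T15B7.3, -4.1) and lys-7 (-3.33). cpr-2 (5.28), thn-1 (4.75), adh-1 (3.80) and acs-2 (2.78) were higher. The oocyte list had a median of 0.26 (30 of 32 members higher, none by 1.5-fold), and autophagy genes one of 0.09 (percentile 99). Pharynx markers (0.38) and heat shock genes (0.19, 4 of 15 at least 1.5-fold higher, not apart at a minimum mean of 200) were above their random lists, with hsp-16.11 (T27E4.2, 1.3) and hsp-70 (C12C8.1, 0.89) higher. The fasting-response list was just above its random lists (0.10, percentile 97.6, not apart at a minimum mean of 200), with 6 members at least 1.5-fold higher and 6 lower. The authors' deposited table called 176 genes, 18 higher and 158 lower.

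Towards the fed library the difference was small: 21 genes were at least 2-fold higher and 24 lower of 9895. These counts were 13 and 45 scaled to the same total and 15 and 34 to the total without rRNA. Inducible heat shock genes were the highest named genes: hsp-16.2 (Y46H3A.3, 54.2 to 218, log2 fold 1.99), hsp-70 (169 to 624, log2 fold 1.87), hsp-16.11 (1.83) and hsp-16.41 (Y46H3A.2, 63.9 to 213, log2 fold 1.72). The heat shock list had a median of 0.26. Its median towards the fasted library, given above, rests on the same day 3 library, and from fed to fasted the list did not stand apart (-0.05, percentile 19.2). Ribosomal proteins (0.23) and hypodermal markers (0.39, not apart at a minimum mean of 10) stood above their random lists. Oocyte genes were lower in the fed library (median -0.35, 5 of 32 at least 1.5-fold lower), led by rme-2 (9522 to 5354, log2 fold -0.83) and puf-5 (5627 to 3331, log2 fold -0.76). lips-13 (-1.74) and scl-20 (ZK384.2, -1.26) were the lowest named genes. The authors' deposited table called 65 genes, 29 higher and 36 lower.

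Genes that differed with the tumour were then set against those that differed with fasting, using the pairs of libraries with no library in common (control to gld-1 RNAi, and fed to fasted). Of 8925 genes measured in both, 60 were at least 2-fold lower in the gld-1 RNAi and at least 2-fold higher in the fasted library, where independent lists would give 6.28. They included the oocyte genes rme-2, puf-5, egg-1, egg-2 and cpg-3 and the embryonic germ granule gene meg-3. Of these, egg-2 and meg-3 were named after the values were seen. Lower in both were 68 genes (17.8 by independence), among them vit-1, vit-3 and vit-4. In the other classes, 16 genes were higher and then lower (27.2) and 6 were higher in both (9.58). The place of these 2 classes against independence turned with the limit. Higher and then lower were 151 against 113.1 genes at 1.5-fold and 7 against 5.22 at 3-fold, and higher in both 24 against 61.2 and 1 against 0.428. The classes lower in the tumour stayed above it, with 227 against 58.9 and 2 against 0.167 for lower and then higher, and 181 against 109 and 10 against 2.04 for lower in both. Across genes, which are not independent replicates, Pearson's r was -0.19 and Spearman's rho -0.38.

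**Figure D3:**
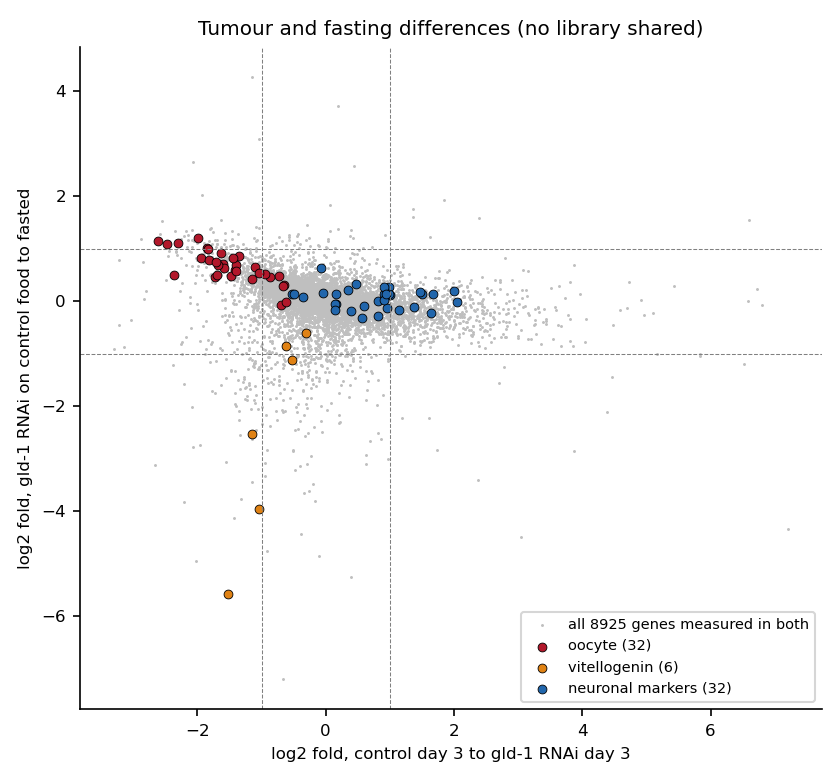
Log2 fold from control to gld-1 RNAi (horizontal) against log2 fold from fed to fasted gld-1 RNAi animals (vertical) for 8925 genes, with dashed lines at 2-fold. The 32 oocyte genes (red) lie on the lower side of the tumour axis and, except for perm-2 and perm-4, above 0 on the fasting axis. The 6 yolk protein genes (orange) lie below 0 on both. Neuronal markers are blue.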

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

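Scaling to the total without rRNA and the count by whole counting intervals were chosen only after the data were seen. Counts of genes past 2-fold moved with the minimum mean, which sets how many low genes enter. At a minimum mean of 10 they were 1972 higher and 1204 lower for control to gld-1 RNAi, 266 higher and 723 lower for fed to fasted, 144 higher and 764 lower for gld-1 RNAi to fasted, 166 higher and 159 lower for gld-1 RNAi to fed, and 4079 lower for young adult to gld-1 RNAi. At a minimum mean of 200 they were 322 higher and 494 lower, 47 higher and 130 lower, 17 higher and 144 lower and 7 higher and 1 lower in the same order, and 1247 lower for the young adult pair. Genes whose whole counting interval lay beyond 2-fold, which removes low genes by construction, numbered 574 higher and 503 lower, 33 higher and 166 lower, 29 higher and 194 lower and 6 higher and 4 lower. Scaled to the same total, young adult to gld-1 RNAi gave 886 higher, with rRNA at 3.53% of the former and 25.7% of the latter total, and gld-1 RNAi to fed gave 13 higher and 45 lower, for which the cause was not tested. A pseudocount of 10 left 14 genes lower in that last pair, since it shrinks low genes. The authors' calls for control to gld-1 RNAi numbered 28 at an adjusted p of 0.05. The gld-1 log2 fold was -3.17 scaled to the total, -3.16 to the upper quartile and -3.21 to the total without rRNA, each a shift common to all genes. Genes past the limit in both the tumour and the fasting pair numbered 583 at 1.5-fold and 20 at 3-fold. Lists that stood apart changed the sign of their median in 17 cases, all with a main median near 0 except the hypodermal list. From gld-1 RNAi to fasted, upper quartile scaling gave 0.0442 for lysosomal genes, 0.0576 for fatty acid synthesis, 0.0893 for glycolysis and 0.0852 for the unfolded protein response. Scaling to the total gave -0.0358 for the respiratory chain and -0.0219 for ribosomal proteins there, and to the total without rRNA -0.0183 and -0.00431. From fed to fasted the respiratory chain was at 0.0201 scaled to the total and 0.018 to the upper quartile. From young adult to gld-1 RNAi, proteasome subunits were at 0.0401 under upper quartile scaling, and from gld-1 RNAi to fed, meiosis genes at -0.0069 and histones at -0.0186 scaled to the total. These scalings shift all genes alike. With a minimum mean of 200, which leaves fewer genes, lysosomal genes were at 0.00382 and fatty acid synthesis at 0.0287 from fed to fasted, and the unfolded protein response at 0.00698 from gld-1 RNAi to fasted. With a minimum mean of 10, which adds low genes, hypodermal markers were at -0.0606 from gld-1 RNAi to fed. Of the other alternatives to list medians, 1121 kept their place against random lists, 19 lost it and 14 gained it. The number of lists apart stayed within 1.5 times in all 31 alternatives. Of those for single named genes, 1883 stayed within the counting interval, 377 went beyond it and none with a 2-fold difference changed sign. Depth limits low genes: at 50 reads in each library the counting interval reaches 0.60 on either side of the log2 ratio. No library could be left out, and no paired analysis was possible because each group has 1 library.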

Other observations

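The tests on tumour growth, age, somatic share, germline share, gld-1 return and loss in the fed animals were chosen only after the result was seen. So was the minimum of 5 genes applied to the test on small nuclear RNA, which replaced a first test on histone genes, themselves part of that pattern.

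Gene families formed by name prefix, an exploratory ranking of 84 families for control to gld-1 RNAi, put the F-box family fbxa highest (median log2 fold 1.01, 33 of 50 members at least 1.5-fold higher, for instance fbxa-140 at 2.46), with the patched-related ptr family (0.74) and the bath family (0.70, bath-36 at 2.99) near the ribosomal proteins. Lowest were the aspartyl proteases of the asp family (-1.05, 8 of 11), the skr family of ubiquitin ligase adaptors (-1.03, 11 of 19), C-type lectins (-0.92, 29 of 45, clec-91 at -2.31), btb (-0.82) and glutathione transferase genes (-0.73). From fed to fasted, 74 families were ranked, and besides col the spp (-0.72), transthyretin-like ttr (-0.63, 14 of 26) and galectin lec families (-0.54, lec-6 at -2.18 and lec-8 at -2.12) were lowest, while FMRFamide-like neuropeptide genes were highest (0.30, 1 of 19 at least 1.5-fold higher). All of these medians kept their sign under the 3 other scalings.

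The young adult and the day 3 control library share food and differ in age, but also in rRNA share (3.53% and 28.1%) and total reads (15426039 and 27547808). On 1 scale over the 5 libraries they differed at many genes: 1690 genes were at least 2-fold higher and 2700 lower in the control, of 10480. Major sperm proteins had a median of -9.38 towards the control (-8.05 with its 22 genes without a read at a floor of 3 reads), and other sperm genes -5.93 (-5.85 with 6 such genes at that floor). Both are lower than from young adult to gld-1 RNAi. For major sperm proteins that order is not decided, since the control and gld-1 RNAi libraries both hold few or no reads. On the scale over the 5 libraries msp-45 stood at 0 and 0.77 and msp-31 at 3.49 and 0.77 in these. The young adult and control libraries both come from animals on control food. Other medians were 1.16 for replication and mitosis, -2.19 for intestinal and -0.95 for neuronal markers and -0.92 for ribosomal proteins. They were -4.86 for col genes, -3.74 for pharynx and -2.63 for muscle markers, and 1.37 for oocyte genes. Scaling to the total, rRNA included, would lower each of them by the same amount (a shift of -0.50).

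With 1 library per group, the authors' p-values have to take the spread from the 2 conditions themselves. A pair that differs more can thus have fewer calls, and the number of calls does not measure how far libraries differ. The number of genes past 2-fold and the number the authors' deposited tables called did not run in parallel over the 5 pairs. They were 45 and 65 for gld-1 RNAi to fed, 366 and 176 for gld-1 RNAi to fasted, 412 and 132 for fed to fasted, 1660 and 47 for control to gld-1 RNAi, and 4446 and 185 for young adult to gld-1 RNAi. Among genes with a mean above 1000, the smallest called log2 fold was 0.55 in the gld-1 RNAi to fed and 2.32 in the control to gld-1 RNAi table.

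A pattern that bears on the young adult comparison is the low share of rRNA in that library, 3.53%, together with low histone reads (median log2 fold 3.46 towards the day 3 control, 22 genes). Tumour growth is argued against by the design, since the day 3 control, on control food, already had an rRNA share of 28.1%. The rRNA share of the gld-1 RNAi library differed from that of the control by -2.39 percentage points, a lower share, with a histone median of 0.00. That comparison does not bear on the young adult library itself. A smaller carry-over of RNA without a poly(A) tail may be the source, but the test by small nuclear and nucleolar RNA rested on 1 measured gene, found too few after its value was seen (log2 fold 1.70) and decides nothing. A general rise of histone transcripts also stays open: the 4 variants taken as tailed had a median of 1.6, with his-71 at -1.3 and his-24 at 3.88. Age cannot be told apart from library preparation, because 1 library came from day 1.

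The neuronal list, at 0.86 from control to gld-1 RNAi, could reflect a smaller share of germline and embryo RNA, which would raise all somatic types alike. The other somatic markers (73 genes of muscle, pharynx, hypodermis and intestine) had a median of -0.15, -0.17 times the neuronal one. The bootstrap range over genes, -0.54 to -0.02, leaves out variation between pools. These values argue against such a share as the whole source. The set joins body wall muscle markers, which stood above their random lists, with intestinal markers, which stood below theirs, so a contribution of that share is not excluded. Long genes did run higher in this pair (median 0.03 in the longest of 4 length classes and -0.18 in the shortest), but among random lists matched on length and expression the neuronal median was at percentile 100 (their central 95%, -0.25 to 0.35). The match used 8 length classes within each of 8 expression classes, so a trend confined to the very longest transcripts is not excluded. A change in neurons was not itself tested, and differences between the 2 libraries other than RNAi remain open. A trait of the day 3 control library is among these, since the neuronal median was -0.95 from young adult to that control. Replicate pools, or RNA of isolated neurons, would be needed to decide.

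The oocyte list, at -1.53 from control to gld-1 RNAi and 0.63 from fed to fasted, had 30 of 32 genes lower in the first and higher in the second pair, all but perm-2 and perm-4. Its median was 1.37 from young adult to the day 3 control, so the first value is not separated from a trait of that control library. For a shift of scale 2 tests were tried after the result was seen and dropped as undecided, since upper quartile scaling moved the fed to fasted pair little and the place among random lists is the pattern itself. A shift of scale would move all genes alike, however. From fed to fasted the median of all genes was 0.04, but the scaling itself holds that value near 0, so it does not test the scale. The distance of the oocyte median from that of 62 other germline genes, 0.02, is the same under any scale. A shift of scale is therefore argued against as the source of that distance, while the value of 0.63 itself stays tied to the scaling. A larger share of germline RNA is argued against by the other germline genes, whose median was 0.0347 times that of oocyte genes. Its bootstrap range over genes, -0.05 to 0.11, leaves out variation between pools. A return of gld-1 mRNA is argued against by its log2 ratio of -0.92, fasted over fed. A loss in the fed animals after day 3 as the whole difference is argued against by a median of 0.26 from gld-1 RNAi to fasted, outside 0.03 to 0.12 for random lists, beside -0.35 to fed. Under upper quartile scaling these were 0.35 and -0.31. Scaling to the total lowers both instead, with the median of all genes going from 0.01 to -0.02 towards fasted and from -0.02 to -0.10 towards fed. How much of the difference lies on each side of the day 3 library therefore depends on the scaling. An effect of food on oocyte transcripts was not itself tested and cannot be separated from a difference between pools with 1 library per group, which replicate pools or dissected gonads would decide.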
